A study of Homo sapiens with 5 samples.

How the data were processed

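RNA from LIN28B and IgG immunoprecipitates of SEM cells was made into directional libraries with a NEB Ultra II kit and sequenced in paired ends on a NextSeq 500, per the labels' protocols. The molecule is given as poly(A) RNA and all libraries share 1 batch in the labels. The submitters' processing notes name FastQC, Trim Galore, STAR and the hg38 build, with no versions. The counting tool, the annotation, the strand setting and the treatment of duplicate and multi-mapping reads are not given in the sources used here. Without molecular identifiers, PCR copies count as reads, so the intervals and floors given here cover counting error only.

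The deposited table holds whole-number counts per gene symbol, not normalized, for 20262 symbols. Of these, 1060 had no value in any library and 51 had a value in IgG library 2 alone (97 counts), and both sets were left out. Of the 20262 symbols, 18976 matched a RefSeq gene, 18872 of them protein-coding. Mitochondrially encoded, small and most long noncoding RNAs were not analysed here. Columns were matched to samples by the library codes in the descriptions, whose numbers differ from the title numbers for IgG. Libraries are named here by title number.

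Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (minimum count 10, minimum total 15, smallest group of 2) were kept, library totals were scaled by TMM, and glmQLFit (robust) and glmQLFTest compared the groups with no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. TMM factors were 1.42 and 1.43 for the IgG and 0.673, 0.813 and 0.901 for the LIN28B libraries. The common dispersion was 1.51, a coefficient of variation of 1.23, with 3 residual degrees of freedom. Standard errors of log2 folds are the fold divided by the root of its F statistic. A gene with no count in a group is given a bound, from 3 counts over that group. It sets the mean of the other group against that floor, so the spread between libraries is not covered. The bound treats reads as independent molecules, so it overstates the fold if few fragments were captured. Intervals of shares are exact Clopper-Pearson at 95%.

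The 30 gene lists, the tests, the alternatives other than those added later and the rule for genes named in the text were fixed before the data were examined. The rule named LIN28B, up to 12 genes per direction with the largest folds past the threshold and all libraries separated, a fixed set of single genes, and up to 4 members per list with the smallest p in the list's majority direction. Other genes named were chosen after their values were seen. Some genes that the rule names are not reported here. The 21 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and with the correlation estimated. Lists of mitochondrially encoded mRNAs, small RNAs and snoRNA hosts had no tested member.

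Alternatives were other scalings, filters and thresholds, DESeq2 1.42.0, limma-voom, glmTreat, fry, each library left out, and replicate numbers as a block. Added after the data were seen were the IgG libraries summed, the genes counted in every library, both together, and TMM factors from those genes. The procedure was tested on simulated counts for the 6577 genes with 100 genes changed per fold size. At a dispersion of 0.1 it recovered 79% of 4-fold and 100% of 16-fold changes, with the common dispersion 0% of either, and with each gene's own dispersion 3% and 23%. In the same order, 9, 0 and 4 unchanged genes were called. Camera called 0 of 20 unshifted simulated lists. Genes were drawn independently there, so this does not test the preset correlation. Estimated correlations of the lists called in the data ran from 0.0762 to 0.443. Figures were drawn with matplotlib 3.10.9.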

Results

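RNA bound to the RNA-binding protein LIN28B was measured by RNA immunoprecipitation and sequencing (RIP-seq) in SEM, a human B-cell acute lymphoblastic leukaemia line that carries the KMT2A::AFF1 fusion. LIN28B blocks maturation of the let-7 microRNAs and also binds many mRNAs. The 5 libraries were 3 LIN28B precipitates and 2 precipitates with a control IgG, and no input library was used here. Counts per library were 362906, 401577 and 435946 for LIN28B libraries 1 to 3, and 237357 and 37241 for IgG libraries 1 and 2. These were shallow libraries with few genes: 6418, 9444 and 5738 genes had a count in the LIN28B libraries, and 3696 and 3308 in the IgG libraries. Of 19151 genes with a value in every library, 12455 had a count in at least 1 library, 1299 had a count in all 5, and 6577 were tested. The labels call the libraries biological replicates, but the IgG libraries held nearly the same genes (Spearman's rho 0.932 across genes, which are not independent replicates, against 0.420 to 0.508 between LIN28B libraries). Their counts still differed by more than sampling noise (chi-square per degree of freedom 2.81, against 24.9 to 29.8 between LIN28B libraries). PCR copies count as reads and can raise this value, so it does not show that the 2 IgG libraries are independent. The main fit counts them as 2 replicates, which makes its p-values too small if they are not. IgG values are given per library with no SD. The calls, list by list, are also given with the IgG libraries summed as 1 sample, an alternative chosen after seeing the data. That fit has no spread within IgG and takes it from the LIN28B libraries. The p-values measure only the spread between these libraries.

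**Figure D1:**
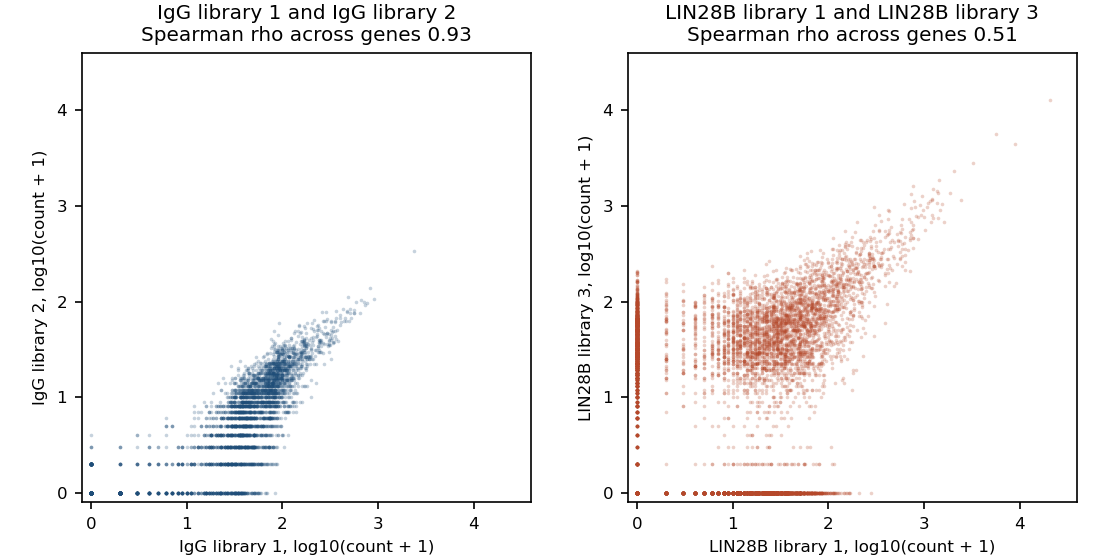
Counts per gene as log10(count + 1) in the 2 IgG libraries (left) and in LIN28B libraries 1 and 3 (right), with 1 point per gene counted in any library. The IgG libraries lie along 1 band with Spearman's rho 0.93, and the LIN28B libraries scatter more widely with rho 0.51, with many genes counted in only 1 of them.

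The comparison of LIN28B with IgG precipitates asked which transcripts LIN28B RIP recovered above the IgG background. H2AZ1, which encodes a histone H2A variant, had a mean of 2028 ± 1015 CPM in LIN28B RIP (SD, n = 3, with counts scaled to the TMM-adjusted library total). It had no count in either IgG library, and its mean was at least 259.9-fold higher, against a floor of 3 counts over the IgG group. Such bounds use the LIN28B mean and leave out the spread between LIN28B libraries, from 870 to 2763 CPM for H2AZ1. EIF2S3, a subunit of translation initiation factor eIF2, was at least 245.7-fold higher, MACF1, a cytoskeletal crosslinker, at least 214-fold, ATP5F1A of the mitochondrial ATP synthase at least 203-fold and the mitochondrial ADP/ATP carrier SLC25A5 at least 180.3-fold. In all, 167 genes were higher and 6 lower in LIN28B RIP at an adjusted p under 0.05 (edgeR quasi-likelihood test), each by 2-fold or more. With the IgG libraries summed, 80 were higher, 79 of them among the 167, and 0 were lower, against 949 and 95 at an unadjusted p under 0.05.

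The other transcripts among the 12 largest increases were the mRNA-decapping enzyme DCP2 (155-fold), the histone methyltransferase KMT2C (149-fold), the splicing factor SRSF2 (141-fold), the plexin PLXNB2 (129.96-fold), the deubiquitinase USP34 (126-fold), the ion channel PIEZO1 (125-fold) and the proteasome activator PSME1 (122-fold), each as a lower bound. Mean levels of the 12 in LIN28B RIP ran from 2028 ± 1015 CPM for H2AZ1 to 956 ± 195 for PSME1 (SD, n = 3). None of the 12 had a count in an IgG library, so each fold was taken against 3 counts over the IgG group (7.80 CPM) and covers counting error only. Genes in IgG library 1 and no LIN28B library had a median of 40 counts, so the folds could be far smaller if few fragments were captured. The rank of the 12 follows LIN28B level alone, and H4C8, at a mean of 1663 CPM with 1 IgG read, falls outside them. Adjusted p-values of the 12 in the edgeR test lay between 0.0371 and 0.0487. With the IgG libraries summed, KMT2C and USP34 no longer passed. H2AZ1 lies on chromosome 4 at 99948088 to 99950275, EIF2S3 on chromosome X at 24054956 to 24078810 and SRSF2 on chromosome 17 at 76734115 to 76737411 (RefSeq annotation of the hg38 build).

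Lower in LIN28B RIP were SOBP, RBM26 (an RNA-binding protein), the ephrin receptor EPHB2, FRMD6, ZKSCAN8 (a zinc finger protein) and the protocadherin PCDH9. The others had no count in a LIN28B library and were at least 138 to 183-fold lower, against 3 counts over the LIN28B group (3.56 CPM). In IgG library 1 they had 125 to 175 counts, where genes absent from every LIN28B library had a median of 40. These folds too could be far smaller if few fragments were captured. PCDH9 had 878 and 1209 CPM in IgG libraries 1 and 2 and 139 ± 39.5 CPM (SD, n = 3) in LIN28B RIP, a log2 fold of -2.90 with an adjusted p of 0.0416. None of the 6 passed with the IgG libraries summed, where PCDH9 had an adjusted p of 0.108 and SOBP 0.0937.

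Among the 167 higher genes, 127 had no count in either IgG library and 40 had one. All 167 had every LIN28B library above both IgG libraries, as had 2071 tested genes, and 51.0% of tested genes were separated in 1 direction or the other against 20% by chance for 5 independent libraries. With the IgG libraries summed as 1 sample, 56.6% lay apart, against 50% by chance. At an unadjusted p under 0.05, 1738 genes were higher and 488 lower. No gene passed when IgG library 1 or any LIN28B library was left out, and 81 were higher and 0 lower without IgG library 2. TMM put the median tested gene at a log2 fold of 3.17 (2.40 with genes at 0 in a group set to their bounds), and of 0.40 among genes counted in every library; with library totals alone these were 2.34 and -0.46 and no gene passed (1414 higher and 666 lower at an unadjusted p under 0.05), so fold changes are relative to that choice.

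Of 74 tested cytosolic ribosomal protein mRNAs, 8 were higher and none lower, and 27 were higher and 1 lower adjusted over the list alone. RPS27A was at 3153 ± 281 CPM (SD, n = 3) in LIN28B RIP against 250.4 and 265 CPM in the IgG libraries, a log2 fold of 3.62 ± 0.32 (SE, adjusted p 0.0371). RPL3 (2.68), RPS3A (3.61) and RPL13A (2.11) had the next smallest p-values. The median log2 fold of the list was 0.98, below that of all tested genes, and was 0.13 with library totals alone. The camera test put the list up (adjusted p 0.00970), but not with an estimated correlation (adjusted p = 0.725). Of 33 translation initiation and elongation factors, EIF2S3, EIF3M and EIF3F were higher (10 adjusted over the list alone), with a median of 1.56 and a camera adjusted p of 0.0170 (adjusted p = 0.725 with an estimated correlation). With the IgG libraries summed, none of the 74 ribosomal protein mRNAs passed (adjusted p 0.0519 for RPS27A), and 2 translation factors did, EIF2S3 (0.0408) and EIF3M (0.0383), but not EIF3F (0.110). With library totals alone neither list was called (camera adjusted p 0.856 and 0.259), and without LIN28B library 1 the translation factors were not (0.0863). Ribosomal protein genes have many processed pseudogenes, and how reads shared with those were counted is not given in the sources used here.

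Splicing factor and hnRNP mRNAs made up another list. Of 53 tested splicing factor and hnRNP mRNAs, 9 were higher and none lower (16 higher adjusted over the list alone; camera adjusted p 0.0154, adjusted p = 0.725 with an estimated correlation). The list's median log2 fold was 1.38, below that of all tested genes. SFPQ, a paraspeckle protein, had 966 ± 241 CPM (SD, n = 3) in LIN28B RIP against 1 read in IgG library 1 and none in IgG library 2. SF3B3, a splicing factor 3b subunit, was at least 77.1-fold higher. With the IgG libraries summed 7 of the 53 were higher, SFPQ and SF3B3 among them (adjusted p 0.0383). The list was not called with library totals alone (camera adjusted p 0.246) or without LIN28B library 1 (0.0752).

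Nuclear-encoded oxidative phosphorylation mRNAs had 4 of 59 higher, ATP5F1A, ATP5F1B, UQCRH and UQCRC2, and none lower (20 higher adjusted over the list alone). ATP5F1B, the ATP synthase beta subunit, was at 1722 ± 743 CPM (SD, n = 3) against 121 and 113 CPM, a log2 fold of 3.87 with an adjusted p of 0.0371, and UQCRH was at least 88.9-fold higher. With genes at 0 in both IgG libraries set to their bounds, the list's median log2 fold was 3.33 (camera adjusted p 0.00998, adjusted p = 0.725 with an estimated correlation, and 0.0649 without LIN28B library 1). With the IgG libraries summed, ATP5F1A (0.0482) and UQCRH (0.0401) passed, and ATP5F1B (0.0818) and UQCRC2 (0.0511) did not.

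Replication-dependent histone mRNAs, which end in a stem-loop in place of a poly(A) tail, gave the smallest camera p of the lists (adjusted p 0.00758, adjusted p = 0.763 with an estimated correlation), but the list was not called without LIN28B library 1 (0.0649). They took 2.16%, 0.408% and 1.08% of counts in LIN28B libraries 1 to 3 and 0.349% and 0.371% in the IgG libraries. H4C8 and H3C4 were higher among 47 tested (13 adjusted over the list alone), and the list's median at bounds was 3.50. H4C8 had 3369, 585 and 1034 CPM in LIN28B libraries 1 to 3 and 1 read in the IgG group. Histone genes are near-identical copies, so reads could be split between them, and neither call held with the IgG libraries summed (adjusted p 0.0666 for H4C8 and 0.0511 for H3C4). Of 33 endoplasmic reticulum chaperone and translocon mRNAs, P4HB, SRP9, RPN1, PDIA3 and SSR1 were higher (14 adjusted over the list alone; camera adjusted p 0.0170, adjusted p = 0.725 with an estimated correlation). P4HB, a protein disulfide isomerase, was at least 74.4-fold higher. P4HB and SRP9 passed with the IgG libraries summed, and RPN1 (0.0511), PDIA3 (0.0519) and SSR1 (0.0513) did not. Of 34 mitosis mRNAs only PRC1, a spindle midzone protein, was higher in the test over all genes (12 adjusted over the list alone), with a median of 2.17, below that of all tested genes, and a camera adjusted p of 0.0459 (adjusted p = 0.725 with an estimated correlation). Neither PRC1 (0.0531) nor the mitosis list (camera adjusted p 0.0508) passed with the IgG libraries summed. Library totals alone ended the call of the ER (camera adjusted p 0.0930) and mitosis lists (0.203), as did leaving out LIN28B library 1 (0.105 for both) and, for mitosis, LIN28B library 3 (0.114).

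Transcripts reported elsewhere as LIN28 targets were tested next. Of 17 tested, 3 were higher, HNRNPF and HNRNPA1 among them, and none was lower (10 higher and 1 lower adjusted over the list alone). HNRNPA1, an abundant splicing regulator, was at 21921 ± 15187 CPM (SD, n = 3) against 923 and 642 CPM, a log2 fold of 4.80 with an adjusted p of 0.0396 (0.0937 with the IgG libraries summed). EEF1A1, translation elongation factor 1 alpha, took 5.71%, 2.17% and 2.95% of LIN28B library counts and 0.998% and 0.900% of IgG library counts, with an adjusted p of 0.0533. The list's median log2 fold was 2.99, against 3.17 for all tested genes as fitted and 2.40 at bounds. Its camera adjusted p was 0.0170 (adjusted p = 0.725 with an estimated correlation) and came out just over the threshold with the IgG libraries summed, where 2 of the 17 were higher. The list was not called with library totals alone either (camera adjusted p 0.0907).

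LIN28B itself had counts of 0, 3 and 57 in LIN28B libraries 1 to 3 and none in the IgG libraries, too few to be tested. Its paralogue LIN28A had 12 counts, all in LIN28B library 2. None of the let-7-regulated oncofetal genes tested passed: IGF2BP1 had 72 and 8 counts in the IgG libraries and none in LIN28B RIP (adjusted p 0.0876), IGF2BP3 had 42, 43 and 0 counts in LIN28B libraries 1 to 3 and none in IgG, and IGF2BP2 had none in any library. HMGA1 had a log2 fold of 2.31 (adjusted p 0.0753), HMGA2 an adjusted p of 0.204 and ARID3A, with no count in LIN28B RIP, 0.113. MYC had a log2 fold of 1.30 (adjusted p 0.204). None of 18 conserved let-7 target mRNAs passed over all genes, and 2 were higher adjusted over the list alone. Camera, which compares a list with the other tested genes, put this list lower (adjusted p 0.721) although its median log2 fold was 1.23. Of 23 let-7 precursors and host genes listed, only 3 were analysed here. Small RNAs were not analysed, so binding of let-7 precursors was not measured. Among let-7 host genes, HUWE1 was higher, with 38 and 8 counts in the IgG libraries and 358, 302 and 325 in the LIN28B libraries (log2 fold 3.21, adjusted p 0.0371, and 0.0861 with the IgG libraries summed), and 2 of the 3 tested were higher adjusted over the list alone.

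Of 27 B-lineage surface and signalling mRNAs, 1 was higher in LIN28B RIP, also with the IgG libraries summed, and none lower (4 higher adjusted over the list alone; camera adjusted p 0.872). None of 26 B-lymphoid transcription factor and recombination mRNAs passed (2 adjusted over the list alone; camera adjusted p 0.904). EBF1 had a log2 fold of 3.37 (adjusted p 0.0578), PAX5 1.34 (0.144) and IKZF1 -1.09 (0.461). Of 26 KMT2A::AFF1 target genes JMJD1C, a histone demethylase family member, was higher, at least 68.4-fold, also with the IgG libraries summed (5 adjusted over the list alone; camera adjusted p 0.335). The antiapoptotic gene BCL2 had no IgG count and an adjusted p of 0.0524. CDK6 had a log2 fold of -0.26 (0.707), MEIS1 an adjusted p of 0.204, and HOXA9 15 counts in LIN28B library 1 alone.

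The remaining lists were not called by camera. Single members were higher in the proteasome (PSMA7 of 23, camera adjusted p 0.0534), DNA replication (MCM3 of 39, 0.583) and aminoacyl-tRNA synthetase lists (IARS1 of 18, 0.371), and FBL and NPM1 among 29 ribosome biogenesis mRNAs (0.0874). Adjusted over the list alone, 9 proteasome, 4 aminoacyl-tRNA synthetase and 10 ribosome biogenesis mRNAs were higher, and 6 DNA replication mRNAs were higher and 2 lower. NPM1, a nucleolar protein, was at 6090 ± 4045 CPM (SD, n = 3) against 314 and 340.1 CPM. MCM3 (0.0401) and FBL (0.0383) passed with the IgG libraries summed, and PSMA7 (0.0511), IARS1 (0.112) and NPM1 (0.103) did not. No member passed among 14 glycolysis (0.0869), 27 microRNA-processing and RNA-binding (0.531), 42 mitochondrial ribosomal protein (0.904), 25 KRAB zinc finger (0.721) or 6 stromal and endothelial mRNAs (0.904), and adjusted over the list alone 5 glycolysis and 1 stromal and endothelial mRNA were higher and none in the other lists. Of other cell types, LCK and ZAP70 of the T cell markers, CEBPA of the myeloid, GYPB and TFRC of the erythroid and TF of the hepatocyte markers were tested, and none passed over all genes (adjusted p 0.101 to 0.303), while adjusted over the list alone 1 T cell marker was higher and 1 erythroid marker lower. Of the nuclear-retained RNAs TUG1 alone was tested (adjusted p 0.862).

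Among the 1299 genes counted in every library, with the IgG libraries summed, 16 genes were higher and 0 lower, a fit and a set of genes chosen after their values were seen (103 higher and 34 lower at an unadjusted p under 0.05). GNAS, the stimulatory G protein alpha subunit, had the smallest p, at 2373 ± 433 CPM (SD, n = 3) against 25.6 CPM in the summed IgG libraries, a log2 fold of 6.50 with an adjusted p of 0.00381 (edgeR). The antioxidant enzyme PRDX1, the ubiquitin ligase UBR4 (log2 fold 4.93), the Mediator kinase module subunit MED13L (4.73) and the phosphate carrier SLC25A3 (16.02-fold) followed, with adjusted p-values of 0.0111 to 0.0178. PRDX1 had only 1 and 2 counts in the IgG libraries, so no fold is given, and the fold of GNAS rests on 4 and 1 IgG counts. Folds of UBR4 (12 and 3), MED13L (16 and 1) and DNMT1 (21 and 1) also rest on few IgG counts. The summed IgG libraries are 1 sample, so the spread behind these p-values comes from the LIN28B libraries alone. Of the 16 genes 14 were among the 167, and PRDX1 (adjusted p 0.0630) and RPL9 (0.0551) were not. The 167 come from the fit that counts the IgG libraries as 2 replicates, so this overlap is not separate support. Of the 14, only GNAS and UBR4 also passed with the IgG libraries summed over all tested genes. HNRNPA1 (4.32), NPM1 (3.95), DNMT1 (3.92), ATP5F1B (3.55), UBB (3.45), IARS1 (3.40), RPS27A (3.38), HSP90AB1 (3.35), RPL9 (3.21), RPS3A (3.17) and MYH9 (3.12) made up the rest.

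**Figure D2:**
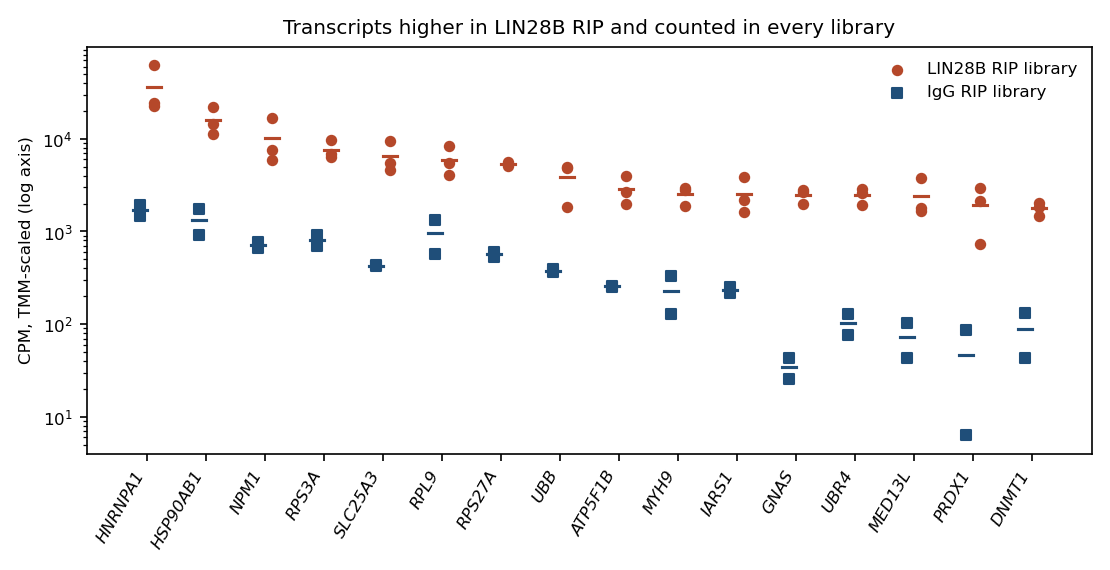
TMM-scaled CPM on a log axis for the 16 genes higher in LIN28B RIP among the 1299 counted in every library, with circles for the 3 LIN28B libraries, squares for the 2 IgG libraries and short lines at group means. The LIN28B libraries lie above both IgG libraries for each gene, and GNAS has a log2 fold of 6.50 over the summed IgG libraries.

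Within those 1299 genes the median log2 fold was 0.08. Reported LIN28 targets had a median of 2.00 over 7 genes (camera adjusted p 0.000359), oxidative phosphorylation mRNAs 1.69 over 9 (0.0286), translation factors 0.97 over 24 (0.00328) and cytosolic ribosomal protein mRNAs 0.64 over 71 (2.98e-06). With an estimated correlation none of these passed (adjusted p = 0.612 to 0.796). The histone (0.237), splicing (0.141) and mitosis lists (0.534), called over all tested genes, were not called here. Camera put the ER list lower than other genes in this fit (adjusted p 0.723), although its median log2 fold over 9 genes was 0.17.

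**Figure D3:**
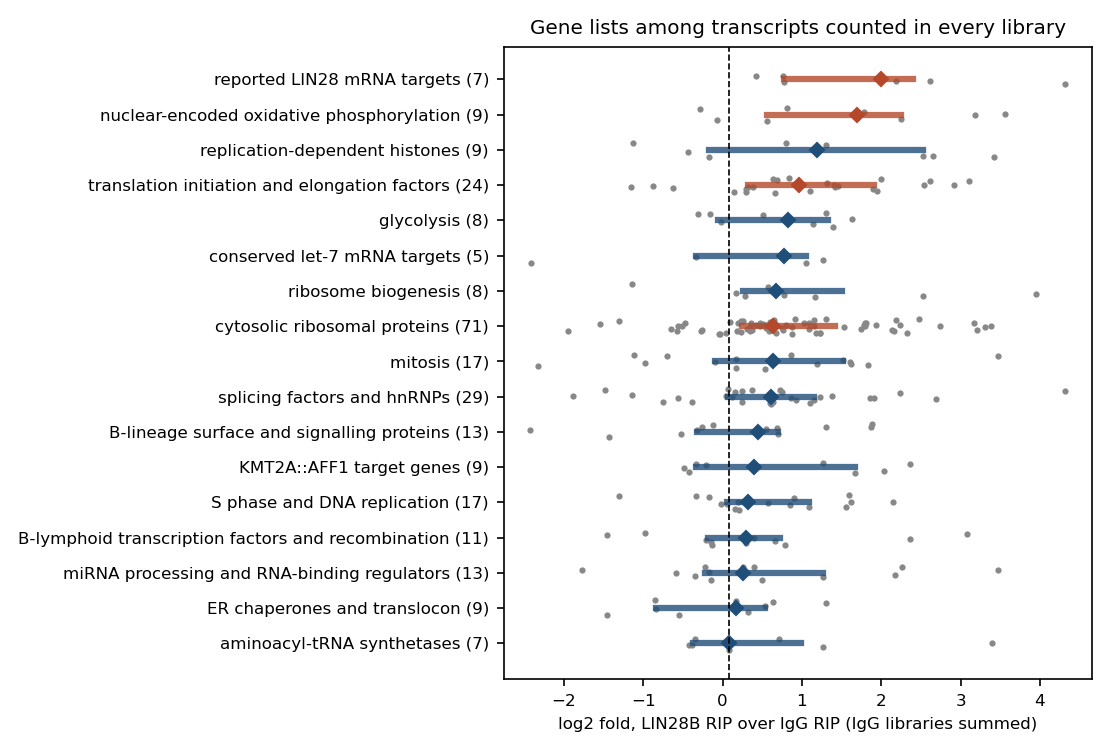
Log2 fold of LIN28B RIP over the summed IgG libraries for members of each gene list among the 1299 genes counted in every library, with a dot per gene, a diamond at the median, a bar over the interquartile range, the number of genes in brackets and a dashed line at the median of all 1299 genes. Lists in red have a camera adjusted p under 0.05 at the preset correlation, and the highest median is that of the reported LIN28 targets at 2.00.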

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

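The settings that sum the IgG libraries, keep the genes counted in every library or take TMM from those genes were chosen after seeing the data. The counts of 167 higher and 6 lower genes, the same at 2-fold, moved under most settings, and where no cause is given the cause was not tested. Higher and lower counts were 0 and 0 with library totals, with upper-quartile factors and at an adjusted p under 0.01 (smallest adjusted p 0.0371), 88 and 5 with median-of-ratios factors, 90 and 5 with TMM from genes counted in every library, 678 and 224 without a filter (675 and 224 at 2-fold), 555 and 18 under a stricter filter that tested 1895 genes (554 and 18 at 2-fold), 1022 and 333 with DESeq2, 578 and 492 with limma-voom, 80 and 0 with the IgG libraries summed, 71 and 25 among genes counted in every library, and 16 and 0 with both. A glmTreat test against 2-fold left 89 and 2. Leaving out 1 library gave 0 to 81 higher and 0 to 0 lower genes, where a lone IgG library was assumed to vary like the LIN28B group. The share of calls that were higher was 96.5%, against 75.2% without a filter, 75.4% with DESeq2, 54.0% with limma-voom and 74.0% among genes counted in every library. The replicate block from the titles gave 483 and 89, and from the library codes 393 and 61 (391 and 61 at 2-fold). Whether the numbers pair the samples could not be tested with 2 IgG libraries, whose deviations mirror each other. Of the 8 called lists, 0 held with an estimated correlation, 0 under the stricter filter, 0 with the replicate block from the library codes (adjusted p 0.0931 to 0.189) and 6 with that from the titles. Library totals, median-of-ratios and upper-quartile factors kept 2 each. The fry tests, which do not compare a list with other genes, kept 7 in the directional form and 8 in the mixed form. The mixed form also called lists that camera did not, such as the conserved let-7 targets (fry mixed adjusted p 0.00103). Camera among genes of average log2 CPM of 4 or more kept 8. Leaving out LIN28B library 1 kept 2, LIN28B library 2 kept 8, LIN28B library 3 kept 7 and either IgG library 8, and 6 held with the IgG libraries summed. The ER list turned down among genes counted in every library (adjusted p 0.606, and 0.723 with the IgG libraries summed), where genes absent from IgG are left out. Size factors from mitochondrially encoded mRNAs were not run, because those genes were not analysed here.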

Other observations

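The tests of the IgG libraries and of the genes absent from them were chosen after the results were seen, as were the matchings on LIN28B and IgG level below. The matching on average level was written before.

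Olfactory receptor transcripts, which B cells are not known to use, were counted in every library. Of 388 receptor genes, 59 had a count in LIN28B library 2 (15.2%, exact interval 11.8% to 19.2%), against 5 in LIN28B library 1 (1.29%, 0.420% to 2.98%), 12 in LIN28B library 3 (3.09%, 1.61% to 5.34%) and 11 in each IgG library (2.84%, 1.42% to 5.02%). LIN28B library 2 also had the most genes with a count, 9444.

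The 2 IgG libraries held nearly the same genes, down to the same 11 olfactory receptor genes, where chance would share 0.312. If every receptor gene were equally likely to be counted, separate precipitates would share them no more than chance. They were shared beyond it (one-sided Fisher's exact p 1.54e-21), while the 3 pairs of LIN28B libraries shared 0 to 2 receptor genes against 0.155 to 1.82 by chance (p 0.564 to 1). Receptor genes took 0.223% and 0.266% of counts in IgG libraries 1 and 2. Separate precipitates whose background holds the same receptor genes at such levels are therefore not excluded. A candidate explanation is that both were read from 1 pool of amplified fragments: of 531 genes in IgG library 1 and no LIN28B library, 84.0% were in IgG library 2, against 93.5% if IgG library 1 were thinned to that depth and 22.5% to 60.8% between LIN28B libraries. The chi-square per degree of freedom of 2.81 is above that of pure resampling, so a shared step before library preparation stays open. No biological explanation was tested.

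Of the 167 higher genes, 127 had no count in either IgG library. The lower read depth of the IgG libraries does not account for this: LIN28B libraries thinned to the depth of IgG library 1 left at most 2.20% of genes at 300 to 1000 CPM without a count, against 25.3% to 31.02% in IgG library 1. Few distinct fragments in the IgG pool remain possible, since genes in IgG library 1 and no LIN28B library had a median of 40 counts. Simulated pools of 5318 fragments drawn from the LIN28B profile with no enrichment gave a median of 4.5 higher calls (0 to 54 over 20 pools, against 167). At an unadjusted p under 0.05 they gave 1400 to 1508 higher genes (against 1738) but only 50 to 83 lower genes (against 488). The pools held a median of 2871 genes, against 3696 in IgG library 1, so they lack part of the IgG content. These values rest on the assumed pool size and profile. Loss of fragments and binding by LIN28B therefore cannot be told apart for these genes without an input library or molecular identifiers.

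Among genes counted in every library, fold rose with abundance (Spearman's rho 0.471 across genes), so each list's median was ranked among 10000 lists matched on average CPM. Matching was within 10 bins of abundance, and a drawn list could include the list's own members. Oxidative phosphorylation mRNAs stood at percentile 99.7 over 9 genes, and at 99.5 and 99.0 when matched on LIN28B or IgG level. A trend with abundance thus gave a lower median in nearly all lists of genes drawn independently. Members of a list can vary together, which these draws leave out, and camera with an estimated correlation did not call the list. The trend is therefore not excluded for their median. Reported LIN28 targets stood at 97.9 over 7 genes, just above the limit set beforehand, but at 96.2 matched on LIN28B level and 99.98 on IgG level; ribosomal protein mRNAs stood at 1.47, 0.015 and 100, and translation factors at 90.3, 77.1 and 99.9. By the matching set beforehand alone, only the LIN28 targets passed the limit among these 3 lists. Ribosomal protein mRNAs lay below nearly all lists matched on average or LIN28B level, where the trend alone gave higher medians than theirs. The level used for matching is itself part of the fold, so for these 3 lists trend and enrichment cannot be told apart.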
